A study of Homo sapiens with 45 samples.

How the data were processed

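SUDHL6 is a human diffuse large B-cell lymphoma cell line of germinal-centre type. Per the labels' protocols, the cells were nucleofected with 80 pmol of a SmartPool, a mixture of siRNAs against 1 transcript, and total RNA was taken 20 hours later. The amount of each pool in the paired silencings is not given in the sources used here. Biotinylated cRNA was hybridised to Illumina HumanHT-12 type BeadArrays, 1 array per sample, 45 arrays in all. Group and replicate number of each array were taken from its title. Titles with the letter A form a separate set, here called set A, with its own controls, and the meaning of the letter is not given in the sources used here. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these arrays, which may be technical.

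The values analysed were the authors' processed log2 values, deposited as 1 table of 45013 probes. They ran from 6.28 to 16.28, and array medians lay between 6.95 and 6.98 on every array but siTFDP1+siATF5 replicate 3. The background correction, the normalization and the exact transformation (plain log2 or a variance-stabilising form of it) are not given in the sources used here, so differences near the lower limit of about 6.9 may be compressed. A second deposited table of raw intensity and detection p-value per probe was not used. Its 45 signal and 45 detection columns are named only by chip and position on 4 chips of 9 to 12 arrays, and no label ties these names to samples. The design fixed beforehand had assumed raw intensities and detection p-values. The authors' log2 values took their place, and a probe counted as above background where it exceeded the array median by more than 0.5 log2 on at least 3 arrays. Chip as a block and quantile normalization of raw intensities could not be run for the same reason.

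Gene names came from the platform annotation supplied with the data. Of the probes, 28746 were listed with 1 gene symbol, 8 with several and 16259 with none. Symbols were compared with a RefSeq gene table (assembly GRCh38.p14), and 0 differed. Of 14524 probes above background, 11089 had 1 symbol, and the probe with the highest mean over all arrays stood for each gene, which gave 8625 genes. No coordinates were used.

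Each comparison was a contrast in 1 linear model with a mean per group, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over 8625 genes, threshold 0.05, no fold threshold). Single silencings were set against siNT4 of the same set and pairs against siNT4+siNT4 of the same set. A pair was called non-additive for a gene where its change differed from the sum of its 2 single changes. Adjusted p below is limma's unless a list test is named. The fit to all 45 arrays is the main result. siTFDP1+siATF5 replicate 3 correlated with the other arrays at a median of only 0.735 and inflated the shared estimate of spread, so each result is also given from a fit of the other 44 arrays, which was chosen after seeing the data. SE is that of the fit named, and SD is over arrays.

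There were 21 gene lists fixed before the data were examined, with 21 of their symbols updated to current ones. Of these, 18 had at least 5 measured members and were tested with limma's camera (preset correlation 0.01) over 198 list and comparison pairs, adjusted together. Each was run again with an estimated correlation and with fry. These were lists of FOXM1-type G2/M genes, E2F-DP type G1/S genes, replication-dependent histones, amino acid response, cholesterol synthesis, MHC class II, unfolded protein response, heat shock, interferon response, p53 target, MYC-type ribosome biogenesis, germinal centre B-cell, B-cell activation and NF-kB, plasma cell, BCL2 family, glycolysis and hypoxia, oxidative phosphorylation and immediate early genes. T-cell, myeloid, and stromal and epithelial markers were fixed as signs of other cells and were too dim to test.

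Genes named were the silencing targets, up to 5 rising and 5 falling genes with the largest change among those past the threshold whose arrays did not overlap between groups, and up to 3 members of each called list. Where no gene passed, the 3 genes of smallest p were named as such. Non-additivity, control and FOXM1 contrasts followed the same rule without the overlap condition. Any other gene is said to have been chosen after its values were seen.

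The fits were tested on simulated data made from the real spread of each gene. For siATF5 against siNT4, 94.4% of genes changed by 1 log2 were recovered with 45 arrays and 100% with 44, and 48.2% and 79.2% of those changed by 0.5. For siHMGA1+siFOXM1 against its 2 control arrays, recovery at 0.5 was 27.6% and 61.6%. Non-additivity of that pair was recovered at 1 log2 in 34% and 72.8% of genes, and at 0.5 in 2.6% and 11%. A simulated fall of 0.15 in the E2F-DP list passed camera at unadjusted p under 0.05 in 10 of 10 runs, and 1 of 10 passed with no change. Genes were drawn independently in these runs, so they do not test how correlation between genes affects the list calls. For arrays no read depth applies, and the number of arrays limits the precision.

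Alternatives listed beforehand were no filter or a filter on every array for dim probes, the mean of all probes of a gene, the replicate number as a block, pooled controls of the set, only the arrays of the contrast, and leaving out each array. Chosen after seeing the data were the 44-array fit, a 43-array fit that also leaves out the library labelled siHMGA1+siTFDP1 replicate 1, for the lists with pooled controls too, leaving out each array from the 44, all controls of the set over 44 arrays for ATF5, quantile normalization of the log2 values, array weights, and, over 44 arrays, the replicate block, a technical block and the share of probes above background as a covariate. No batch is given in the labels. As a stand-in, arrays were put in 4 blocks of 12 consecutive samples of the series (the last of 9), because the first principal component over 44 arrays, with 28.2% of the variance, set most of block 1 (4.29 to 21.0) apart from blocks 2 to 4 (-11.0 to 4.32). Whether these blocks match the chips is not known. The contrast of the set A controls cannot be fitted with them, because no group links block 4, which holds its siNT4 arrays, to the other blocks. Overlap and list correlation of siATF5 and siTFDP1 were also set against 100 simulations of unchanged groups drawn from whole-array residuals of the 44-array fit, added after seeing the data. The draws were random over groups and blocks and did not keep the block layout of the real groups. No 2 arrays held identical values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.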

Results

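Candidate regulators of the change from follicular lymphoma to diffuse large B-cell lymphoma were silenced in SUDHL6 cells, singly and in pairs, and transcript levels were measured 20 hours later. The targets were HMGA1, a chromatin architectural protein, FOXM1, a forkhead factor of G2/M genes, TFDP1, the dimerisation partner of E2F factors, ATF5, a stress-responsive bZIP factor, and NFYB, a subunit of the CCAAT-binding factor NF-Y. The first set held 30 arrays. Of these, siHMGA1, siFOXM1, siTFDP1 and siATF5 had 3 each, and the non-target control siNT4 had 4. Among the pairs, siHMGA1+siFOXM1 and siHMGA1+siATF5 had 3 each, siHMGA1+siTFDP1 had 4, siTFDP1+siATF5 had 2, and the doubled control siNT4+siNT4 had 2. Set A held 15 arrays, 3 each of siNFYB, siFOXM1, siNT4, siNFYB+siFOXM1 and siNT4+siNT4. The series design speaks of triplicates, while the titles give groups of 2 to 4.

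On 44 arrays, between 24.2% and 30.6% of probes were above background, and the median correlation of an array with the others was 0.973 to 0.992. In siTFDP1+siATF5 replicate 3 the share was 44.5% and the median correlation 0.735. Of the markers of other cells, 0 of 10 T-cell markers were above background, as were 2 of 9 myeloid markers with a probe, CD14 at a median log2 of 7.19 and FCGR3A at 7.64. VIM, at 10.2, was the 1 such stromal or epithelial marker. Lymphoma lines can express VIM.

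Silencing was checked on the targets first. HMGA1 fell by 1.55 log2 in siHMGA1, from 11.43 ± 0.11 (SD, n = 4) to 9.87 ± 0.24 (SD, n = 3), with adjusted p = 5.3e-07 with 45 arrays and 3.7e-12 with 44 in limma. It also fell by 1.39 in siHMGA1+siATF5 (adjusted p = 4.5e-04 and 3.6e-08, and 0.0611 with 45 arrays without siNT4+siNT4 replicate 3). In siHMGA1+siFOXM1 the change was -1.06, past the threshold with 44 arrays (adjusted p = 4.8e-05) and not with 45 (0.0656). TFDP1 fell by 1.06 in siTFDP1, from 11.33 ± 0.08 (SD, n = 4) to 10.28 ± 0.09 (SD, n = 3), with adjusted p = 0.0051 and 2.0e-09. With 45 arrays it did not pass without siTFDP1 replicate 1 (-1.01, adjusted p = 0.13) or 2 (-1.07, 0.0514). ATF5 was at 10.12 ± 0.08 (SD, n = 3) in siATF5 against 10.81 ± 0.11 (SD, n = 4), a change of -0.69 with adjusted p = 0.105 with 45 arrays and 0.0028 with 44, and 0.0404 with 45 arrays without siATF5 replicate 3. With 44 arrays the adjusted p was 0.0513 without siATF5 replicate 2. With the share of probes above background as a covariate over 44 arrays, ATF5 had -0.77 and did not pass. FOXM1 did not pass in any group. Its change was -0.27 (SE 0.10) in siFOXM1, -0.19 (SE 0.11) in siFOXM1 of set A, -0.38 (SE 0.12) in siHMGA1+siFOXM1 and -0.26 (SE 0.11) in siNFYB+siFOXM1. A second, dimmer FOXM1 probe gave -0.0107, -0.0476, -0.16 and -0.20 in these groups. NFYB lay near the lower limit in every group, at 7.30 ± 0.19 (SD, n = 3) in siNFYB and 7.37 ± 0.06 (SD, n = 3) in its control, so its probe checks nothing.

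**Figure D1:**
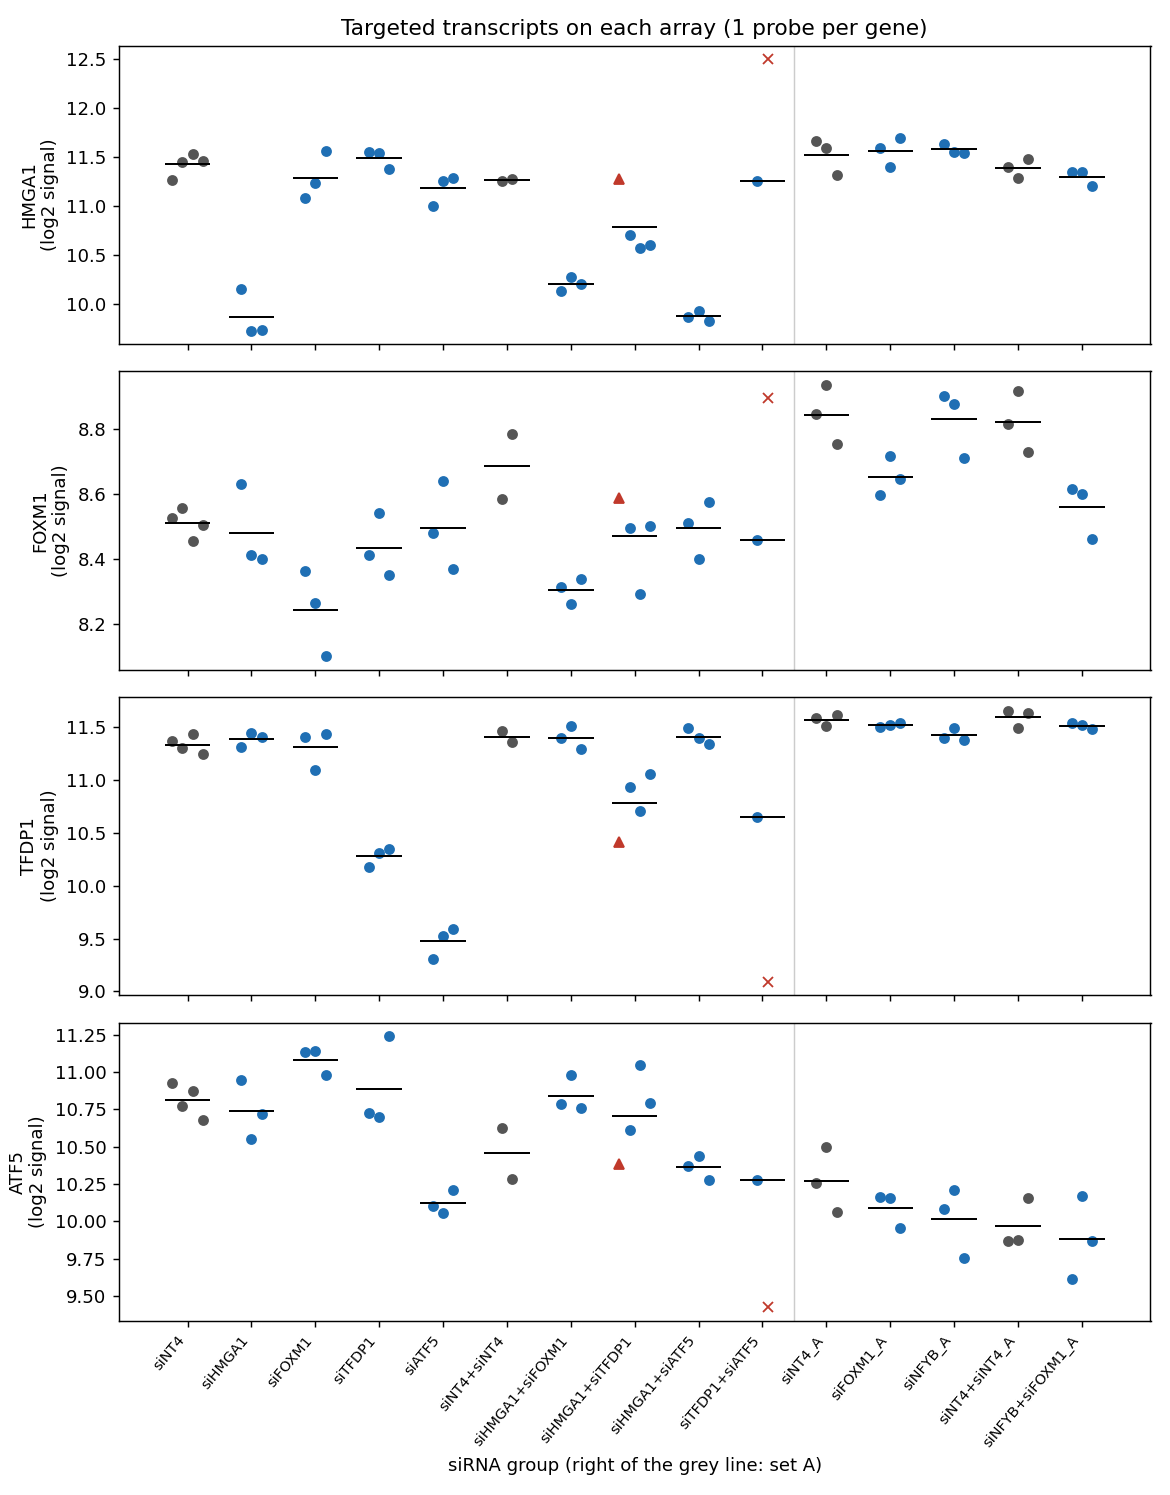
Log2 signal of HMGA1, FOXM1, TFDP1 and ATF5 (y axes) on each of the 45 arrays, by siRNA group (x axis). Grey points are non-target controls, blue points silenced arrays, the red cross siTFDP1+siATF5 replicate 3 and the red triangle the library labelled siHMGA1+siTFDP1 replicate 1, and lines are group means without the cross. TFDP1 lies lower in siATF5 (mean 9.47) than in siTFDP1 (mean 10.28), and HMGA1 of the triangle (11.27) lies in the range of siNT4 (11.27 to 11.53).

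In siHMGA1+siTFDP1 the target goes against the label of 1 array. HMGA1 was 11.27 in the library labelled siHMGA1+siTFDP1 replicate 1, against 10.58 to 10.70 in the other 3 and 11.27 to 11.53 in siNT4. TFDP1 was 10.41 there, against 10.71 to 11.06 in the other 3. Directions given below for this pair rest in part on that library. Values without it follow for HMGA1, TFDP1, CCAR1 and the gene lists named in the pair.

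TFDP1, which that pool does not name, fell in siATF5 by 1.86 log2, further than in siTFDP1. Its level was 9.47 ± 0.15 (SD, n = 3) against 11.33 ± 0.08 in siNT4 (SD, n = 4), with adjusted p = 8.6e-09 with 45 arrays and 5.3e-18 with 44. A second TFDP1 probe gave -1.90. The direct difference between siATF5 and siTFDP1 was -0.81 (SE 0.11), past the threshold with 44 arrays (adjusted p = 2.6e-05) and not with 45 (0.164). Within blocks of consecutive arrays the siATF5 change was -1.92 and -1.74. In siHMGA1+siATF5, TFDP1 stayed within its control's range of error, at 11.41 ± 0.08 (SD, n = 3) against 11.41 ± 0.07 (SD, n = 2).

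Replication genes lay lower in siATF5. Among the 32 measured E2F-DP type G1/S genes, which are needed to start and carry out DNA synthesis, 28 had a negative change, and the mean was -0.31 log2 (camera adjusted p = 1.3e-11 with 45 arrays and 2.4e-12 with 44). With an estimated correlation the call was lost with 45 arrays (adjusted p = 0.497) and held with 44 (adjusted p = 8.4e-05). RRM2, a subunit of ribonucleotide reductase, fell by 0.59, and MCM10, a replication initiation factor, fell by 0.54 (adjusted p = 0.0466 for both with 45 arrays). Neither passed with 45 arrays without siATF5 replicate 1 or 2 or any 1 siNT4 array. RRM2 was near the lower limit of signal already in siNT4 (7.45 to 7.71). With 44 arrays 12 members fell over all genes tested and 20 when adjusted over the list alone, against 2 and 10 with 45. Over all genes it was 4 with 44 arrays without siATF5 replicate 2. They included the helicase subunit MCM4 (-0.76, adjusted p = 4.2e-04), thymidylate synthase TYMS (-0.76, 2.1e-04) and cyclin E1, CCNE1 (-0.73, 0.0014). A second MCM4 probe (mean level 9.69) gave only -0.26. A second CCNE1 probe, near the lower limit (mean level 7.02), gave 0.44. Mean list changes within blocks were -0.33 and -0.26. With the share of probes above background as a covariate over 44 arrays the mean was -0.26 as well, while RRM2 (-0.47, adjusted p = 0.572) and MCM10 (-0.39, 0.494) did not pass. With that covariate 0 list members fell past the threshold over all genes, so MCM4, TYMS and CCNE1 lost their calls too.

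Mitotic genes lay lower in the same arrays. The 30 FOXM1-type G2/M genes changed by a mean of -0.20 (camera adjusted p = 1.1e-05 with 45 arrays and 3.0e-05 with 44), with 24 negative. The call was lost with an estimated correlation (adjusted p = 0.672 and 0.171). With 44 arrays 8 members fell over all genes and 18 adjusted over the list alone, against 0 and 10 with 45. The counts with 44 arrays were 0 and 9 without siATF5 replicate 1, and likewise without replicate 2. Over all genes the count was 3 and 2 without siNT4 replicates 2 and 4, and 16 without siATF5 replicate 3. Examples with 44 arrays were HMMR, a spindle-associated protein (-0.52, adjusted p = 0.0182), the spindle factor DLGAP5 (-0.46, 0.0095) and the centrosomal kinase NEK2 (-0.46, 0.0215). Within blocks the mean was -0.28 and -0.10. With the share of probes above background as a covariate it was -0.12 (camera adjusted p = 1.3e-04), and HMMR (-0.19), DLGAP5 (-0.23) and NEK2 (-0.22) did not pass (adjusted p = 0.997 for each). The amino acid response list, fixed for ATF5, was not called (mean -0.08, camera adjusted p = 0.332 and 0.472). With 44 arrays ATF3, a stress-induced factor of that list, rose by 0.50 (adjusted p = 0.0019) and MTHFD2, a mitochondrial folate enzyme, fell by 0.39 (0.0274), besides ATF5 itself. Both were named after their values were seen.

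Over all genes 4 changed in siATF5 with 45 arrays, 1 up (SMPD1, acid sphingomyelinase, 0.53, adjusted p = 0.0466) and 3 down (TFDP1, RRM2, MCM10). SMPD1 was near the lower limit in siNT4 (6.98 to 7.16), and a second, dim probe gave -0.09. RRM2 was also low there (7.45 to 7.71), so the sizes of these 2 changes are uncertain. With 44 arrays 512 changed, 240 up and 272 down. ZNF546, SLC27A6, MAGED4B, CCR8 and FAM200B were among the rises, from control levels of 6.93 to 7.70, near the lower limit, so their sizes are not ranked. The share of probes above background was 29.4% and 30.6% on siATF5 replicates 1 and 2, 25.4% on replicate 3 and 25.2% to 25.9% in siNT4. With that share as a covariate 2 of the 512 passed, TFDP1 (-1.78) and MYB (-0.67), a B-cell and progenitor transcription factor, and the 5 rises just named had 0.12 to 0.66. With 44 arrays the count was 19 without siATF5 replicate 2, 80 without replicate 1, 1747 without replicate 3, and 191 and 293 without siNT4 replicates 4 and 2. With 45 arrays it was 152 without siATF5 replicate 3 and 1 without any other of the 7 arrays.

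The same cell-cycle groups lay lower in siTFDP1. The E2F-DP list changed by a mean of -0.16 (camera adjusted p = 2.0e-05 with 45 arrays and 3.8e-06 with 44), with 26 of 32 members negative. With an estimated correlation the call was lost with 45 arrays (adjusted p = 0.888) and held with 44 (adjusted p = 0.0092), though not without siTFDP1 replicate 3 (0.0601). The G2/M list changed by -0.18 (adjusted p = 2.3e-07 and 8.1e-07, 26 of 30 negative), a call lost with an estimated correlation (adjusted p = 0.596 and 0.0708). Within blocks the means were -0.15 and -0.18 for E2F-DP genes and -0.20 and -0.17 for G2/M genes. Glycolysis and hypoxia genes had a mean of 0.14 in siTFDP1, with 18 of 20 positive (camera adjusted p = 9.7e-04 and 0.0030), a call lost with an estimated correlation (adjusted p = 0.982 and 0.484). It was also lost without siNT4 replicate 2 (mean 0.07, camera adjusted p = 0.194 with 45 arrays and 0.231 with 44) and without siTFDP1 replicate 3 (0.10, 0.0795 and 0.127). Within blocks it was 0.15 and 0.17, but in block 1 siNT4 replicate 1 (10.35) lay between the 2 siTFDP1 arrays (10.28 and 10.41), so the 0.15 comes from siNT4 replicate 2 (10.03). None of its members passed, over all genes or adjusted over the list alone. The direct difference of siATF5 from siTFDP1 with 44 arrays was -0.15 in the E2F-DP list (camera adjusted p = 1.0e-04, and 0.0139 as adjusted p with an estimated correlation, which was 0.0629 without siTFDP1 replicate 1 and 0.0873 without siATF5 replicate 3). In the glycolysis list, whose mean of -0.12 in siATF5 was not called, it was -0.26 (camera adjusted p = 4.0e-06), a call lost with an estimated correlation (adjusted p = 0.278). In the G2/M list it was -0.0254 and not called (camera adjusted p = 0.719).

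**Figure D2:**
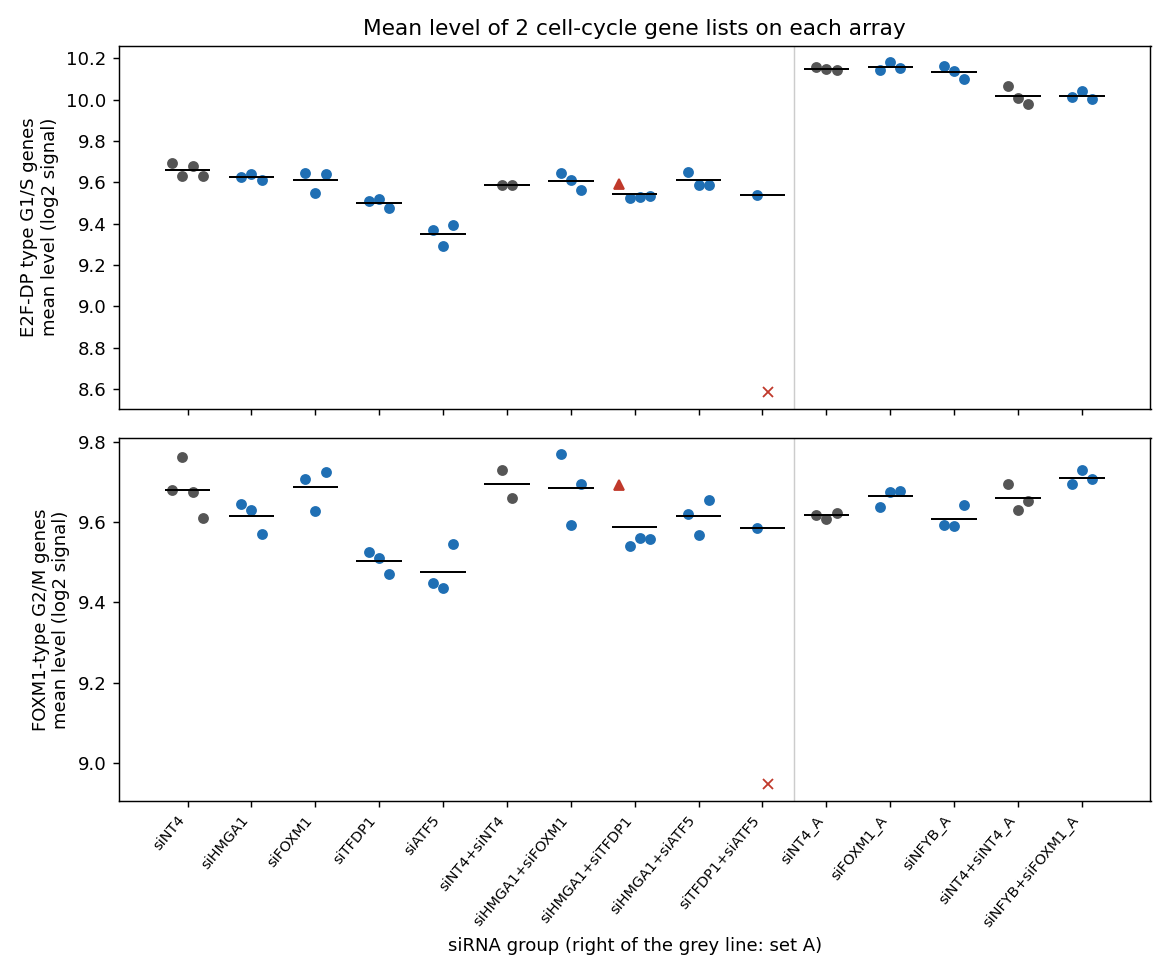
Mean log2 level of 32 E2F-DP type G1/S genes (top) and 30 FOXM1-type G2/M genes (bottom) on each of the 45 arrays, by siRNA group, with symbols and lines as in the plot of target levels. In the top panel siATF5 (mean 9.35) and siTFDP1 (9.50) lie below siNT4 (9.66), and all set A groups lie above 10.0.

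Of single genes, TFDP1 was the 1 that passed in siTFDP1 with 45 arrays, and 7 passed with 44. Besides TFDP1, NEK2 (-0.63, adjusted p = 0.0131), TYMS (-0.57, 0.0193), DPY19L4 (-0.54, 0.0414) and RHOT1, a mitochondrial transport GTPase (-0.51, 0.0093), fell, and the complement inhibitor CD59 rose (0.42, 0.0414). RHOT1 had -0.20 with 45 arrays when its probes were averaged, so its change rests on 1 probe. STMN1, a microtubule-destabilising protein named after its values were seen, also fell (-0.51, 0.0093). Adjusted over the list alone with 44 arrays, 9 E2F-DP and 7 G2/M members fell, against 1 of each over all genes. With 45 arrays these counts were 3 and 3 against 0 and 0. Without siTFDP1 replicate 3 the G2/M count with 44 arrays was 4. The 44-array count of all genes was 2 to 4 on leaving out any 1 of the 7 arrays other than siNT4 replicate 3, and 11 without that. NEK2 did not pass without siTFDP1 replicate 2 or 3 or siNT4 replicate 2 or 4, nor TYMS without siTFDP1 replicate 2 or 3 or siNT4 replicate 1 or 2. DPY19L4 passed in 0 of these 7 fits and CD59 in 1, that without siNT4 replicate 3. Without siTFDP1 replicate 3 or siNT4 replicate 2 the count was 2 with TFDP1 among them, so RHOT1 and STMN1 did not both pass. With 45 arrays the count was 0 without siTFDP1 replicate 1 or 2.

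Falls shared by siATF5 and siTFDP1 with 44 arrays were TFDP1, NEK2, STMN1 and TYMS, 4 against 0.189 for independent lists, and CD59 was the 1 shared rise, against 0.0278. Both comparisons use the same siNT4 arrays. In 100 simulations of unchanged groups that share controls, the top lists of these sizes shared a mean of 1.81 falls and 0.31 rises, and 9 and 31 of them shared as many as observed. With different siNT4 arrays for each comparison, TFDP1 was shared in all 6 assignments and STMN1 in 1. Across genes, which are not independent replicates, their changes correlated at r = 0.553 (covariance 0.0156). The mean of 100 other simulations of unchanged groups, with each gene drawn independently, was 0.429 (0.0058). These simulations lack the correlation between genes on real arrays, and their spread is not given. They do not show whether 0.553 is unusual. With different siNT4 arrays for each, r was 0.319 (0.0105) as a mean of 6 assignments, from 0.144 to 0.393 (0.0054 to 0.0122).

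HMGA1 was the only gene past the threshold in siHMGA1, with 45 and with 44 arrays. The G2/M list changed by a mean of -0.07, with 26 of 30 members negative (camera adjusted p = 0.0127 with 45 arrays and 0.0119 with 44). Members were small in change, as in KIF20A, a mitotic kinesin (-0.19, SE 0.09 with 44 arrays), and 0 passed, over all genes or adjusted over the list alone. The list call was lost with an estimated correlation (adjusted p = 0.987 and 0.426). It was also lost without siNT4 replicate 2 (mean -0.0391, camera adjusted p = 0.278 with 45 arrays and 0.236 with 44) or siHMGA1 replicate 3 (-0.0434, 0.263 and 0.219), so the call rests on these 2 arrays.

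After siFOXM1, glycolysis and hypoxia genes had a higher mean, a difference that rests in large part on 2 arrays. Of 20 measured members 17 had a positive change, and the mean was 0.17 log2 (camera adjusted p = 5.2e-05 with 45 arrays and 2.0e-04 with 44), with group means of 10.42 ± 0.12 (SD, n = 3) and 10.25 ± 0.16 (SD, n = 4). The call was lost without siNT4 replicate 2, which was at 10.03 against 10.24 to 10.37 in the other 3 (mean 0.10, camera adjusted p = 0.0568 with 45 arrays and 0.0770 with 44). It was also lost without siFOXM1 replicate 3, which was at 10.55 against 10.33 and 10.37 (0.10, 0.12 and 0.136). With 44 arrays the members adjusted over the list alone were 4 rises, ALDOC (0.62), ADM (0.31), ENO1 (0.25) and LDHA (0.25), and 0 over all genes. Adjusted over the list alone 0 passed without siFOXM1 replicate 2 or siNT4 replicate 3, 1 without siFOXM1 replicate 3 and 2 without siFOXM1 replicate 1 or siNT4 replicate 2. ALDOC, ENO1 and LDHA are glycolytic enzymes. The list call was lost with an estimated correlation too (adjusted p = 0.764 and 0.405). MHC class II genes, which present antigen, changed by a mean of 0.13, with 10 of 11 positive (camera adjusted p = 0.0147 and 0.0097). HLA-DMA, a peptide-loading chaperone, had 0.26 (SE 0.12) and CD74, the invariant chain, 0.17 (SE 0.10) with 44 arrays. That call was lost too (adjusted p = 0.596 and 0.0708 with an estimated correlation), and 0 members passed, over all genes or adjusted over the list alone. Without siFOXM1 replicate 3 it was lost with 45 arrays (mean 0.14, camera adjusted p = 0.0531) and held with 44 (0.0369). Within blocks the means were 0.11 and 0.13 for MHC class II genes. For glycolysis they were 0.16 and 0.25, but in block 1 siNT4 replicate 1 (10.35) lay between the 2 siFOXM1 arrays, so the 0.16 comes from siNT4 replicate 2, and in block 2 siFOXM1 replicate 3 is the 1 silenced array. The G2/M list, fixed for FOXM1, was not called (mean 0.0054, median -0.0187, adjusted p = 0.778 and 0.731). Adjusted over the list alone, 1 member fell with 45 arrays, and 2 rose and 1 fell with 44, against 0 over all genes.

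In siFOXM1 0 genes passed in limma with 45 or 44 arrays, with 301 and 910 at unadjusted p under 0.05, and 93 passed with 44 arrays without siFOXM1 replicate 3. Of the smallest p, none of which passed, NEK2 had -0.60 (adjusted p = 0.561 and 0.0792), SMAP2, a regulator of vesicle traffic, 0.42 (0.966 and 0.0954) and ENTPD6 0.58 (0.966 and 0.0792). With probes averaged NEK2 had -0.31 and SMAP2 0.24. Set A repeated this silencing. In that set MHC class II genes were at 10.55 to 10.60 on the siFOXM1 arrays and 10.55 to 10.60 in siNT4. There 0 genes passed in limma (60 and 196 at unadjusted p under 0.05), and TTLL12 (-0.37) and PAWR (0.45) were among the smallest p, with adjusted p = 0.9998 for both with 45 arrays. Unfolded protein response genes changed by a mean of -0.08, with 14 of 16 negative (camera adjusted p = 0.0084 and 0.0124, lost with an estimated correlation at adjusted p = 0.764 and 0.0601). That call was lost without siFOXM1 replicate 1 of set A (-0.07, 0.0568 and 0.0747) or siNT4 replicate 2 of set A (-0.06, 0.136 and 0.173). Changes in the sets correlated across genes at r = 0.06 only. No gene differed between the sets in limma (0, with 111 and 415 at unadjusted p under 0.05), and 0 passed over both sets together (176 and 547), where SMAP2 had 0.35 (adjusted p = 0.457 and 0.0527). With 44 arrays 3 differed between the sets without siFOXM1 replicate 3 of the first set, and SMAP2 passed over both sets without siFOXM1 replicate 1 or 2 of the first set or replicate 3 of set A.

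In siNFYB 0 genes passed in limma (39 and 142 at unadjusted p under 0.05). Of the smallest p, TNIP1, an inhibitor of NF-kB signalling, had -0.40 (SE 0.14) and the tetraspanin CD82 -0.35 (SE 0.11; -0.15 with probes averaged), neither past the threshold. Glycolysis and hypoxia genes changed by a mean of -0.10, with 15 of 20 negative (camera adjusted p = 0.0236 and 0.0227). The call was lost with an estimated correlation (adjusted p = 0.987 and 0.628) and against the pooled controls of set A (mean -0.0054, adjusted p = 0.985). It was also lost without siNFYB replicate 3 (-0.06, camera adjusted p = 0.597 and 0.524) or siNT4 replicate 1 (-0.06, 0.426 and 0.298) or 2 (-0.09, 0.123 and 0.0956) of that set.

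Pairs with siHMGA1 were set against siNT4+siNT4, which has 2 arrays. Glycolysis and hypoxia genes lay higher in each. The mean was 0.32 in siHMGA1+siATF5, with 20 of 20 members positive (camera adjusted p = 4.8e-17 with 45 arrays and 1.1e-14 with 44). In siHMGA1+siTFDP1 it was 0.25 with 19 of 20 positive (4.1e-13 and 1.0e-11), and in siHMGA1+siFOXM1 0.24 with 16 of 20 (1.0e-06 and 5.2e-06). In siHMGA1+siATF5 PFKFB3, an activator of glycolysis, had 0.64 (SE 0.14) and the glucose transporter SLC2A1 0.43 (SE 0.14) with 44 arrays, where 8 members passed adjusted over the list alone and 0 over all genes. The 8 became 0 without siNT4+siNT4 replicate 2 and 1 without siHMGA1+siATF5 replicate 2. Adjusted p with an estimated correlation was 0.0670 and 0.0601, 0.136 and 0.0708, and 0.596 and 0.310 for the 3 pairs, so each call was lost. The controls differ in this list themselves, by -0.24 in siNT4+siNT4 against siNT4 (camera adjusted p = 5.2e-12 and 4.7e-10) and by -0.28 in the 1 block with both. Within blocks the mean was 0.33 and 0.32 for siHMGA1+siATF5, 0.14 and 0.26 for siHMGA1+siTFDP1 and, in the 1 block with both groups, 0.35 for siHMGA1+siFOXM1. Against the siNT4 and siNT4+siNT4 arrays together the means were 0.16 (adjusted p = 7.7e-06), 0.08 (0.0032) and 0.08 (0.117). Without the library labelled siHMGA1+siTFDP1 replicate 1, which is not in the blocks compared, the mean in that pair was 0.21 (camera adjusted p = 3.5e-07, and 0.306 as adjusted p with an estimated correlation). Against all these controls it was then 0.0495 and no longer called (adjusted p = 0.223).

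MHC class II genes lay higher in siHMGA1+siFOXM1, with a mean of 0.15 and 9 of 11 positive (camera adjusted p = 0.0236 and 0.0233). They also lay higher in siFOXM1 of the first set, but not in siFOXM1 of set A (10.55 to 10.60 against 10.55 to 10.60 in siNT4). In the pair the members went both ways. HLA-DRA, an antigen-presenting chain, had 0.30 (SE 0.11) and HLA-DPB1, another, had -0.29 (SE 0.10) with 44 arrays, and each passed when adjusted over the list alone, where 0 passed over all genes and 0 of either kind with 45. Over the list alone 0 passed without siHMGA1+siFOXM1 replicate 1 or 2 or siNT4+siNT4 replicate 3, and 5 without siHMGA1+siFOXM1 replicate 3. Without that replicate the silenced arrays are of block 1 and the controls of blocks 2 and 3, so block and silencing cannot be told apart. With blocks of 12 in the model over 44 arrays the list mean was 0.11. The list call was lost with an estimated correlation (adjusted p = 0.600 and 0.16) and against all controls of the set (mean 0.09, adjusted p = 0.0972). It was lost too without siHMGA1+siFOXM1 replicate 2 (0.13, camera adjusted p = 0.0688 with 45 arrays and 0.0699 with 44) or siNT4+siNT4 replicate 3 (0.13, 0.0760 and 0.0796), and with 45 arrays without siNT4+siNT4 replicate 2 (0.16, 0.0515). G2/M genes changed by -0.11 in siHMGA1+siTFDP1, with 28 of 30 negative (camera adjusted p = 1.9e-04 and 3.6e-04), and by -0.08 in siHMGA1+siATF5, with 23 negative (0.0233 and 0.0355). Adjusted p with an estimated correlation was 0.870 and 0.309, and 0.987 and 0.490. Without siNT4+siNT4 replicate 2 neither was called, with means of -0.07 (camera adjusted p = 0.0690 and 0.0600) and -0.05 (0.332 and 0.365), and siHMGA1+siATF5 was not called without its replicate 2 (-0.06, 0.176 and 0.236). Without the library labelled siHMGA1+siTFDP1 replicate 1 the mean in that pair was -0.14. The E2F-DP list was called in none of these pairs, with means of 0.02, -0.04 and 0.02, the second being -0.0588 without that library.

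Of single genes, HMGA1 was the 1 that passed in siHMGA1+siATF5 with 45 and with 44 arrays, and ATF5 had -0.10 (SE 0.20) there. ATF5 was 10.29 and 10.63 in the 2 control arrays and had 0.08 without siNT4+siNT4 replicate 2, -0.27 without replicate 3, -0.05 without siHMGA1+siATF5 replicate 3, and -0.33 (SE 0.16) against all controls of the set (adjusted p = 0.9998 with 45 arrays and 0.695 with 44, unadjusted p = 0.0460 and 0.0199). With 45 arrays that count was 0 without siNT4+siNT4 replicate 3 and 2 without siHMGA1+siATF5 replicate 2. With 44 it was 2 and 3 without siHMGA1+siATF5 replicates 2 and 3. With 45 arrays 0 passed in siHMGA1+siFOXM1 in limma (240 at unadjusted p under 0.05) and 0 in siHMGA1+siTFDP1 (77). With 44, HMGA1 passed in the former and TFDP1 in the latter (-0.63, adjusted p = 0.0157). In the latter 0 genes passed without either siNT4+siNT4 array or siHMGA1+siTFDP1 replicate 4. Without siHMGA1+siFOXM1 replicate 3 the count in that pair was 66. That fit sets arrays of block 1 against controls of blocks 2 and 3, so block and silencing cannot be told apart in it. Of the smallest p, CCAR1, a regulator of cell cycle and apoptosis, had -0.70 in siHMGA1+siFOXM1 and -0.60 in siHMGA1+siTFDP1, neither past the threshold, and 0.61 in siNT4+siNT4 against siNT4. Without the library labelled siHMGA1+siTFDP1 replicate 1, the changes in that pair were -0.64 for HMGA1 and -0.51 for TFDP1, against -0.48 and -0.63 with it, and CCAR1 had -0.56. Without it 0 genes passed in the 43-array fit.

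siTFDP1+siATF5 rests on 2 arrays, of which replicate 3 stands apart. With both, 4602 genes passed, 1243 up and 3359 down, and without replicate 3, 0 passed in limma, with 258 at unadjusted p under 0.05. Without replicate 2, 7084 passed, and 2297 and 2210 without either control array. Replicate 2 alone, taken to vary like the other groups, had TFDP1 at -0.76 (SE 0.16, adjusted p = 0.260) and ATF5 at -0.18 (SE 0.22, adjusted p = 0.999). Its glycolysis and hypoxia genes had a mean of 0.40, with 19 of 20 positive (camera adjusted p = 2.3e-13, and 0.0601 as adjusted p with an estimated correlation). With 45 arrays that mean was 0.12 (-0.16 without replicate 2), and it was -0.04 against all controls of the set. Oxidative phosphorylation genes had a mean of -0.61 with 45 arrays and -0.10 with 44 (camera adjusted p = 0.0233 and 0.0106), a call lost with an estimated correlation (adjusted p = 0.987 and 0.346). It was lost too without siNT4+siNT4 replicate 2 (-0.56, camera adjusted p = 0.0575 with 45 arrays, and -0.06, 0.224 with 44) and without siTFDP1+siATF5 replicate 2 (-1.11, 0.0822). With 44 arrays alone, cholesterol synthesis genes (mean 0.17), G2/M genes (-0.11) and heat shock genes (-0.14) were also called (camera adjusted p = 0.0124, 0.0060 and 0.0361), each lost with an estimated correlation (adjusted p = 0.309, 0.365 and 0.309). Without siNT4+siNT4 replicate 3 cholesterol synthesis (0.16, 0.0721) and heat shock genes (-0.13, 0.198) were not called, nor G2/M genes without its replicate 2 (-0.07, 0.0797). With 45 arrays these means were -0.38, -0.43 and -0.53, and -0.92, -0.75 and -0.92 without siTFDP1+siATF5 replicate 2.

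In siNFYB+siFOXM1 of set A SMAP2 rose by 0.54 with 44 arrays (adjusted p = 0.0220), from 9.47 ± 0.06 (SD, n = 3) to 10.00 ± 0.06 (SD, n = 3). It did not pass on leaving out any 1 of the 6 arrays (0 genes each). With 45 arrays 0 genes passed in limma (65 at unadjusted p under 0.05), and SMAP2 had adjusted p = 0.224, with a change of 0.28 when its probes were averaged. Unfolded protein response genes changed by a mean of -0.09, with 15 of 16 negative (camera adjusted p = 0.0072 and 0.0106), among them the chaperone HYOU1 (-0.33, SE 0.11 with 44 arrays). Ribosome biogenesis genes changed by -0.07 with 17 of 20 negative (0.0272 and 0.0193), heat shock genes by -0.10 with 9 of 11 negative (0.0376 and 0.0252), and G2/M genes by 0.05 (0.0272 and 0.0403). These calls were lost with an estimated correlation, at adjusted p = 0.764 and 0.0601, 0.982 and 0.342, 0.982 and 0.309, and 0.987 and 0.505. Glycolysis and hypoxia genes had 0.09 (0.0233 and 0.0310, and 0.987 and 0.630 as adjusted p with an estimated correlation). Each call was lost on leaving out some single arrays. With 45 arrays unfolded protein response genes had -0.08 without siNT4+siNT4 replicate 1 of set A (camera adjusted p = 0.0688), and ribosome biogenesis genes -0.07, -0.06, -0.07 and -0.07 without siNFYB+siFOXM1 replicates 2 and 3 and siNT4+siNT4 replicates 2 and 3 (0.0943, 0.176, 0.169 and 0.0884). Heat shock genes had -0.10, -0.10, -0.09 and -0.08 without siNFYB+siFOXM1 replicates 1, 2 and 3 and siNT4+siNT4 replicate 2 (0.0583, 0.0870, 0.104 and 0.301), and G2/M genes 0.04 and 0.04 without replicate 2 of either group (0.151 and 0.242). Glycolysis genes had 0.03 without siNFYB+siFOXM1 replicate 2 (0.691), 0.08 without siNT4+siNT4 replicate 1 (0.146) and, still called, 0.15 without siNFYB+siFOXM1 replicate 1. With 44 arrays ribosome biogenesis genes without siNT4+siNT4 replicate 3 and heat shock genes without siNFYB+siFOXM1 replicate 1 were called, while G2/M genes without replicate 3 of either group (0.0543 and 0.0769) and glycolysis genes without siNT4+siNT4 replicate 2 (0.0595) were not. Against the pooled controls heat shock genes had -0.05 (adjusted p = 0.485) and glycolysis genes -0.0015 (0.938).

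Few non-additive changes were called, and the power to call them was low. In simulations for siHMGA1+siFOXM1, a departure of 0.5 log2 was recovered in 2.6% of genes with 45 arrays and 11% with 44. The low counts therefore do not show that few genes were non-additive. With 45 arrays 0 genes passed in limma for each of the 5 pairs, with 58, 76, 151, 1742 and 46 at unadjusted p under 0.05 for siHMGA1+siFOXM1, siHMGA1+siTFDP1, siHMGA1+siATF5, siTFDP1+siATF5 and siNFYB+siFOXM1. In siTFDP1+siATF5 the count was 6 without siATF5 replicate 3 and 5466 without its own replicate 2. With 44 arrays TFDP1 passed in both pairs with siATF5. It lay 1.81 (SE 0.21, adjusted p = 5.2e-07) above the sum of the singles in siHMGA1+siATF5 and 2.16 (SE 0.24, adjusted p = 9.9e-08) above it in siTFDP1+siATF5, where TYMS also passed (1.36, SE 0.27, adjusted p = 0.0341). Without siATF5 replicate 3 these counts of 1 and 2 were 49 and 177. TFDP1 alone passed in siTFDP1+siATF5 without siATF5 replicate 1, siTFDP1 replicate 3, siNT4 replicate 1, 2 or 4 or siNT4+siNT4 replicate 3, and 4 genes passed without siNT4+siNT4 replicate 2. The siTFDP1+siATF5 values rest on replicate 2 alone, taken to vary like the other groups. Both sums take in the siATF5 change in TFDP1 (-1.86), and whether those arrays also held TFDP1 siRNA is not settled by these data. Over all genes the changes of first-set pairs correlated with those of a single sharing a target at a median r of 0.164 with 45 arrays and 0.0290 with 44. With an unrelated single the median was 0.0534 in both. For siTFDP1+siATF5, r with siTFDP1 and siATF5 was 0.254 and 0.416 with 45 arrays, and -0.0254 and -0.132 with 44. The set A pair, left out of these medians, had -0.0407 with siNFYB and 0.0328 with siFOXM1. Pair and single use different control arrays.

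The control groups set the background for these differences. siNT4+siNT4 did not differ from siNT4 in any single gene in limma (0, with 74 and 269 at unadjusted p under 0.05). In set A ADI1, an enzyme of methionine salvage, rose by 0.79 and HSPA6, an inducible heat shock protein, by 0.78 in siNT4+siNT4 against siNT4 (adjusted p = 0.0293 for both with 45 arrays), and with 44 arrays BLNK, a B-cell receptor adaptor, also rose (0.91, adjusted p = 0.0283). With probes averaged over 45 arrays HSPA6 had 0.44 (adjusted p = 0.702) and ADI1 0.79 (0.0515). With 45 arrays this count of 2 was 0 without siNT4+siNT4 replicate 1 or 3 or siNT4 replicate 2 or 3 of the set, and 1 without either of the others. With 44 arrays the count of 3 was 0 without siNT4+siNT4 replicate 3 or siNT4 replicate 2, 1 without siNT4+siNT4 replicate 2 or siNT4 replicate 3, and 5 without siNT4+siNT4 replicate 1. All siNT4 arrays of set A lie in block 4 and its siNT4+siNT4 arrays in blocks 2 and 3, so in this contrast block and group cannot be told apart, for genes or lists. The E2F-DP list differed by -0.13 between these set A controls (camera adjusted p = 2.4e-04 and 8.9e-05), a call lost with an estimated correlation with 45 arrays (adjusted p = 0.715) and held with 44 (0.0186), though not without siNT4+siNT4 replicate 2 (0.0586) or 3 (0.0863) or siNT4 replicate 1 (0.0982). Glycolysis genes differed by -0.18 there (1.9e-04 and 4.5e-04), lost with an estimated correlation (adjusted p = 0.715 and 0.417), as was the first set's difference (0.0851 and 0.107, and 0.0093 with 44 arrays without siNT4 replicate 2). Of 36 list tests between controls, 3 were called with 45 arrays and 3 with 44. Of 198 list tests in silencings, 24 and 30 were called, of which 0 and 2 held with an estimated correlation.

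The other lists were called in few comparisons or none. Besides the call in siTFDP1+siATF5, cholesterol synthesis genes had a mean of 0.13 in siHMGA1+siATF5 and 0.09 in siNFYB+siFOXM1, called with 44 arrays alone (camera adjusted p = 0.0124 and 0.0355), and germinal centre B-cell genes had 0.10 in siHMGA1+siATF5 (0.0297 with 44 arrays). In siHMGA1+siATF5 cholesterol synthesis was not called without siHMGA1+siATF5 replicate 2 (0.07, 0.246) or siNT4+siNT4 replicate 3 (0.12, 0.125). Germinal centre genes were not called without siNT4+siNT4 replicate 2 (0.05, 0.531) or siHMGA1+siATF5 replicate 3 (0.09, 0.103), and had 0.15 without siNT4+siNT4 replicate 3. In siNFYB+siFOXM1 cholesterol synthesis was called without siNT4+siNT4 replicate 3 and not without any other 1 of the 6 arrays (0.0542 to 0.231). With 45 arrays cholesterol synthesis was called without siHMGA1+siATF5 replicate 3 (0.17, 0.0454) and, in siNFYB+siFOXM1, without siNT4+siNT4 replicate 3 (0.10, 0.0492), as were germinal centre genes without siNT4+siNT4 replicate 3 (0.15, 0.0331). None of these lists held with an estimated correlation (adjusted p = 0.309, 0.365 and 0.309 with 44 arrays). Heat shock genes had -0.14 in siHMGA1+siFOXM1, with 8 of 11 negative, and -0.11 with blocks of 12 in the model over 44 arrays. Their call (camera adjusted p = 0.0324 and 0.0361) was lost with an estimated correlation (adjusted p = 0.982 and 0.309). They were not called without siHMGA1+siFOXM1 replicate 1 (-0.12, 0.109 and 0.107) or 2 (-0.12, 0.0564 and 0.0662) or siNT4+siNT4 replicate 3 (-0.13, 0.156 and 0.127), nor with 44 arrays without siNT4+siNT4 replicate 2 (-0.14, 0.0703). In no silencing were the histone, interferon response, p53 target, plasma cell, BCL2 family, B-cell activation and NF-kB, or immediate early lists called. Their lowest camera adjusted p with 45 arrays were 0.270, 0.0763, 0.451, 0.314, 0.505, 0.674 and 0.431.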

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

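The test for TFDP1 siRNA in the siATF5 arrays, both tests of the library labelled siHMGA1+siTFDP1 replicate 1, the simulated correlation, and every value over 44 arrays were chosen after the results were seen.

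Mean levels of 3 gene lists had 1 array apart from the other 3 of siHMGA1+siTFDP1, by Dixon's ratio. G2/M genes were at 9.6934 and E2F-DP genes at 9.5923 in the library labelled siHMGA1+siTFDP1 replicate 1, against 9.5415 to 9.5611 and 9.5254 to 9.5322 in the others. Histone genes were at 9.2917 in replicate 4, against 9.1968 to 9.2081. These were 3 of 71 values tested, and chance flags about 1 in 20 groups, so the number is about what chance gives. HMGA1 (ratio 0.8223), TFDP1 (0.4605) and ATF5 (0.3810) were among the values not flagged in this group.

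HMGA1 in that library was 11.27, within the siNT4 range, against 10.58 to 10.70 in the other 3. Failed delivery of both siRNAs is argued against by TFDP1, which lay -0.8346 from the lowest siNT4 array, while failure of the HMGA1 siRNA alone stays open. A wrong label may account for it and stays open too, with siTFDP1+siATF5 as the candidate, since that group has no replicate 1 (nor has siNT4+siNT4) while siHMGA1+siTFDP1 has 4 arrays. ATF5, at 10.38, lay -0.3180 from the lowest of 9 arrays of block 1 not given siATF5 (SD 0.17), but siNT4+siNT4 replicate 3, of another block and not given siATF5 either, was at 10.29, so ATF5 does not settle it. The library was kept under its label, and moving it would change both pairs, with 3 arrays in each.

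E2F-DP genes and TFDP1 lay lower in siATF5 than in siNT4. With blocks of 12 arrays in the model the list mean was -0.3088, and with the share of probes above background it was -0.2630, so neither accounts for it alone. Loss of TFDP1 is a candidate explanation. Over the list the siATF5 and siTFDP1 changes correlated at 0.6584 with split controls (mean of 6 assignments, 0.4789 to 0.7441). The highest of 100 simulations of unchanged groups was 0.414. These drew arrays at random over groups and blocks, while both real groups have 2 arrays in block 1 and 1 in block 2. They cannot exclude a shared effect of block or array quality on this correlation. In siHMGA1+siTFDP1 TFDP1 also fell (-0.63), but the list mean was only -0.04. In siTFDP1+siATF5 replicate 2 TFDP1 had -0.76, and the list was at 9.54 against 9.59 on both control arrays. TFDP1 siRNA in the siATF5 arrays stays open: TFDP1 lay 1.8617 higher in siHMGA1+siATF5 than in siATF5 relative to controls, but whether the pool acted in that pair is not settled, since ATF5 had -0.10 against 2 controls, 1 of them low (siNT4+siNT4 replicate 3, 10.29), and -0.33 (unadjusted p = 0.0460 with 45 arrays and 0.0199 with 44, adjusted p = 0.9998 and 0.695) against all controls of the set. Whether ATF5 acts on TFDP1, or the pool on TFDP1 directly, was not tested.

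Array quality may account for most other siATF5 calls over 44 arrays. With the share of probes above background in the model, 2 of 512 passed. The mean absolute change of the 512 went from 0.43 (mean SE 0.11) to 0.21 (mean SE 0.13), so on average the estimates shrank. The 512 were picked by the first of these fits, which can itself make their mean smaller in another model. No unselected genes were compared. With blocks of 12 in the model instead, the mean was 0.41. The shrinkage does not hold for each gene: ATF5 lost its call while its change went from -0.69 to -0.77. That share was highest on 2 of the 3 siATF5 arrays, so it is partly confounded with the silencing.

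Arrays were also regrouped into groups of the same sizes. For siTFDP1 1 of 35 splits, the real one, gave as many genes, the smallest share these splits allow. With 44 arrays (7, highest other 3), a fit chosen after seeing the data, the target TFDP1 is 1 of the 7. That count was 2 to 4 without any 1 array of the contrast other than siNT4 replicate 3. Chance is thus not firmly excluded for it. With 45 arrays (1, highest other 0) the count is TFDP1 itself and was 0 without siTFDP1 replicate 1 (adjusted p = 0.13) or 2 (0.0514), so little rests on it. Chance was not excluded for siATF5, with 2 of 35 splits in each fit (4, highest other 4, and 512, highest other 908). The split with 908 genes put siATF5 replicates 1 and 2 with siNT4 replicate 1, all of block 1, which points to a structure of the samples. For siHMGA1 the count of 1, HMGA1 itself, was matched in 2 of 35 splits with 45 arrays (highest other 1) and in 8 of 35 with 44 (highest other 27), so chance was not excluded for the count. A tie at a count of 1 does not test the change in HMGA1, which passed on leaving out any 1 of the 7 arrays (-1.69 to -1.48). With a real count of 0 every split is as large by construction, which says nothing of chance. This holds for siFOXM1, with 35 of 35 splits (0, highest other 0 and 82). The splits with 27 and 82 genes also grouped block 1 arrays alone. With blocks of 12 in the model the counts were 657 for siATF5, 1 for siHMGA1 and 5 for siFOXM1. It also holds for the 100 of 100 drawn splits for non-additivity of siNFYB+siFOXM1 (0, highest other 0 and 1), the FOXM1 difference between sets (0, highest other 0 in both fits) and the FOXM1 change over both sets (0, highest other 0 and 2). With 3 arrays against 3, the 10 splits are too few for a share under 0.05. There siFOXM1, siNFYB and, with 45 arrays, siNFYB+siFOXM1 of set A gave 0 (highest other 0, 10 of 10 splits). With 44 arrays siNFYB+siFOXM1 gave 1 (highest other 0, 1 of 10), and the set A controls gave 2 and 3 (highest other 0, 1 of 10 in both fits). The real split of these controls follows the blocks, and no blocked value can be had.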

How the results depend on the processing

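All values over 44 or 43 arrays, the quantile, weight, block and quality alternatives were chosen after seeing the data. Quantile normalization of raw intensities and the chip block were not run, because raw columns could not be assigned to arrays, and the authors' processed values are the main values themselves. Over all alternatives, target changes kept direction and side of the threshold in 254 cases, gained it in 21, lost it in 20 and changed sign in 3. List means did so in 478, 46, 116 and 11 cases, and named genes in 1550, 154, 71 and 2. Counts of genes stayed within 1.5 times in 316 cases and moved in 113. The cause was not tested, except that leaving out arrays or genes changes what is tested.

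The counts for siFOXM1 and siNFYB of set A, non-additivity of siHMGA1+siFOXM1, siHMGA1+siTFDP1 and siNFYB+siFOXM1, and the FOXM1 difference between sets were 0 under every alternative run, leaving out 1 array from the 44 aside. With 44 arrays that FOXM1 difference was 3 without siFOXM1 replicate 3 of the first set. For siATF5 (4) the count was 7 with no filter, 13 with all controls, 512 with 44 arrays, 539 with 43, 2 after quantile normalization, 179 with weights, 657 with blocks of 12, 2 with the quality covariate and 1 to 152 leaving out 1 array. For siTFDP1 (1) it was 2 with the every-array filter and with all controls, 7 with 44 and 43 arrays, 15 with weights, 16 with blocks of 12, 5 with the quality covariate, 3 with only its arrays and 0 to 1 leaving out 1 array. For siTFDP1+siATF5 (4602) it was 8518 with no filter, 1927 with the every-array filter, 0 with 44 arrays, weights, blocks of 12, the quality covariate and only its arrays, 1 with 43, and 0 to 7084 leaving out 1 array. Weights gave 2 for siHMGA1 and 35 for siFOXM1, which had 5 with blocks of 12 and 1 with the quality covariate.

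For siHMGA1+siFOXM1 (0) the count was 2 with blocks of 12, and 1 with the every-array filter, all controls, 44 or 43 arrays, weights, the quality covariate and only its arrays. For siHMGA1+siTFDP1 (0) it was 1 with 44 arrays and the quality covariate and 3 with weights and blocks of 12. For siHMGA1+siATF5 (1) it was 2 with all controls, 0 after quantile normalization, 6 with weights, 4 with blocks of 12 and the quality covariate, and 0 to 2 leaving out 1 array. For siNFYB+siFOXM1 (0) it was 1 with 44 or 43 arrays, weights, blocks of 12, the quality covariate and only its arrays. Non-additive genes in siHMGA1+siATF5 (0) were 2 with blocks of 12, and 1 with 44 or 43 arrays, quantile normalization, weights, the quality covariate and only its arrays. In siTFDP1+siATF5 (0) they were 2 with 44 or 43 arrays and blocks of 12, 1 after quantile normalization and with the quality covariate, and 0 to 5466 leaving out 1 array. First-set controls (0) gave 1 with blocks of 12. Set A controls (2) gave 0 with no filter, mean probes or quantile normalization, 1 with the every-array filter, 3 with 44 arrays, 13 with 43, 141 with weights, 18 with the quality covariate, 173 with only their arrays and 0 to 1 leaving out 1 array, and could not be fitted with blocks of 12, which coincide with these groups. FOXM1 over both sets (0) gave 9 with weights, 2 with blocks of 12 and 1 with the quality covariate.

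Replicate numbers were not taken to pair the arrays. Over 12 comparisons same-number correlations ran from -0.26 to 0.38, and none with 3 pairs had each over 0.1. In 2 comparisons with 2 pairs, siHMGA1+siFOXM1 and siNT4+siNT4 against siNT4, each was over 0.1. Deviations from means of so few arrays depend on each other, so this check cannot show that replicates were unpaired. In siTFDP1 all 3 arrays correlated best with their own number, which is a hint from the data and not from the design. With the replicate block over 45 arrays the count was 1 for siATF5, 4 for set A controls and 1 for non-additivity of siTFDP1+siATF5. Over 44 arrays the block gave 449 for siATF5, 9 for siTFDP1, 1 for siFOXM1, siHMGA1+siFOXM1, siNFYB+siFOXM1, FOXM1 over both sets and non-additivity of siHMGA1+siATF5, 3 for siHMGA1+siATF5, 0 for siTFDP1+siATF5, 10 for its non-additivity and 48 for set A controls. Under that block ATF5 in siATF5 was -0.63, HMGA1 in siHMGA1+siFOXM1 -1.07, and in siTFDP1+siATF5 TFDP1 -0.75, ATF5 -0.18 and the cholesterol list 0.1852.

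ATF5 in siATF5 (-0.69, not past) passed with 44 and 43 arrays and only its arrays (-0.69), weights (-0.6864) and blocks of 12 (-0.6868). It did not pass with the quality covariate (-0.7662). HMGA1 in siHMGA1+siFOXM1 (-1.06, not past) passed with the every-array filter, 44 or 43 arrays and only its arrays (-1.06), all controls (-1.17), weights (-1.0686), blocks of 12 (-1.11) and the quality covariate (-1.04). In siHMGA1+siTFDP1 HMGA1 passed with weights (-0.60), and TFDP1 with 44 arrays (-0.63), weights (-0.53), blocks of 12 (-0.5971) and the quality covariate (-0.64). HMGA1 in siHMGA1+siATF5 lost its call after quantile normalization (-1.39). In siTFDP1+siATF5 TFDP1 lost its call with 44 arrays (-0.76), weights and only its arrays (-1.54), blocks of 12 (-0.72) and the quality covariate (-0.7601), and ATF5 with 44 or 43 arrays (-0.18), weights and only its arrays (-0.61), blocks of 12 (-0.24) and the quality covariate (-0.1771), and it turned after quantile normalization (0.0298). Leaving out 1 array gave -1.09 to -1.01 for TFDP1 in siTFDP1, -0.74 to -0.65 for ATF5 in siATF5, -1.42 to -1.36 for HMGA1 in siHMGA1+siATF5, and in siTFDP1+siATF5 -2.32 to -0.76 for TFDP1 and -1.03 to -0.18 for ATF5. It turned NFYB in siNFYB (-0.16 to 0.0320) and ATF5 in siHMGA1+siATF5 (-0.27 to 0.0763).

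Other changes of sign were in siTFDP1+siATF5, except 1. Non-additivity of TYMS (0.43) turned after quantile normalization (-0.4468) and without replicate 2 (-0.4996), and was 1.36 without replicate 3. The cholesterol list (-0.38) turned with 44 or 43 arrays and without replicate 3 (0.1720), with blocks of 12 (0.1591) with the quality covariate (0.1675) and with 43 arrays against all controls (0.1274), and was -0.92 without replicate 2. The glycolysis list (0.12) turned with all controls (-0.0427) and without replicate 2 (-0.1568), and was 0.40 without replicate 3. In siNFYB+siFOXM1 the glycolysis list (0.09) turned with all controls (-0.0015), with 45 and 43 arrays alike. Genes near the lower limit of signal, NFYB among them, have no usable level at this signal over background.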

Other observations

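Comparisons of all silenced with all control arrays, and the test of SMAP2 against chance among genes, were chosen after the results were seen.

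SMAP2, a GTPase-activating protein of vesicle traffic, lay higher in silenced than in control arrays. Over 44 arrays the lowest silenced array was at 9.75 and the highest control array at 9.67. The mean difference was 0.40 log2 (SE 0.05, limma adjusted p = 4.788e-07 with 44 arrays and 7.1e-05 with 45). Group means were 9.84 to 10.07 in silenced groups and 9.47 to 9.64 in the 4 control groups. In the same contrast 5 genes passed with 44 arrays, SMAP2 up and TFDP1, HMGA1, PAGR1 and NEK2 down. With 45 arrays 2 passed, SMAP2 and TFDP1 (adjusted p = 0.01), and HMGA1 (0.145), PAGR1 (0.179) and NEK2 (0.103) did not. They were named after their values were seen.

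A difference between blocks of 12 arrays is argued against, since SMAP2 lay higher within each block, by 0.2555 at the least. The limma adjusted p of 4.788e-07 allows for the number of genes. The contrast was chosen after the results of the same arrays were seen, so this p does not exclude chance. A probe artifact stays open, since a second, dimmer SMAP2 probe (mean 7.68) differed by 0.1162. An effect of the non-target siRNA on SMAP2 may give the same pattern as an effect of silencing, and no untreated array was analysed here.

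E2F-DP genes had a mean level of 10.15 in siNT4 of set A and 9.66 in siNT4 of the first set. What else differed between the sets is not given in the sources used here, so no comparison was made.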
